A study of Drosophila melanogaster with 4 samples.

How the data were processed

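Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an antibody against histone H3, a core histone of nucleosomes. Nuclei came from wild-type 3rd instar larvae of the Oregon-R strain of *Drosophila melanogaster*. The series holds 4 libraries, 2 from H3 ChIP and 2 from input chromatin, which was not immunoprecipitated. Per the labels' protocols, tissue was fixed with formaldehyde and the chromatin was sheared by sonication before immunoprecipitation. The labels name input 1 as the input of ChIP 1 and input 2 as the input of ChIP 2. They do not say whether the replicates came from separate cultures of larvae, so the spread between them may be technical.

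The submitters' processing notes name Bowtie 0.12.7, a read aligner, and positions are on FlyBase r5, per the file headers. The program that called the regions, its thresholds, the scaling of ChIP to input and the handling of repeated sequence are not given in the sources used here. The authors deposited 3 lists of regions of significant enrichment or depletion, 1 for each ChIP replicate and 1 for the replicate set, called the combined list here. That the last covers both ChIP replicates was taken from its name as a replicate set; how it was made is not given in the sources used here. Each region has a first base, a last base and a value. The values were taken as log2 enrichment of ChIP over input, as the authors deposited them. No header names the unit, and the scale was read from the values. Among the 40 highest values of each list, the difference between distinct values was the log2 of a ratio of whole numbers, with a denominator of at most 100 and a tolerance of 1e-08, in 55 of 55 pairs of the combined list, 449 of 496 pairs of replicate 1 and 343 of 406 pairs of replicate 2. On a natural log scale 0 pairs of any list had such a ratio, and on a log10 scale 1, 7 and 3 pairs did. Whether a value is the mean or the maximum over its region is not given in the sources used here. Regions labelled enriched had values above 0 in all lists, and regions labelled depleted had values below 0.

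The files give no read counts, so the depth of the libraries is unknown and no interval for the log2 values of single regions could be made. Confidence intervals of shares of regions are 95% Wilson intervals. They cover counting error only and treat regions as independent, which neighbouring regions are not. No input values were used apart from the authors' own ratio, so ChIP could not be compared with background measured separately.

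Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Coverage was computed per base over 13 arms of the assembly: the 6 main arms (2L, 2R, 3L, 3R, X and 4), 6 arms of mapped heterochromatin (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet) and U, which joins scaffolds with no chromosomal position. Arm lengths came from the file headers. Uextra, a further set of unplaced scaffolds, had no region in any list and was left out of the assembly length. Regions labelled enriched are called clusters, and the depleted regions were treated separately.

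A cluster counted as shared when clusters of the other list covered at least 50% of its length. Overlap, coverage of arms and coverage near centromeres were tested against 1000 circular shifts, which keep the widths and the spacing of clusters. Shifts were drawn over the whole length; a narrower range, used at first, had called too many simulated lists with no change, and it was replaced after coverage by arm and near centromeres had first been computed. Shifts stayed within an arm for the overlap and for the position along an arm, and ran over the joined arms for the distribution between arms. The smallest p-value these shifts can give is 0.001 one-sided and 0.002 two-sided. Two-sided tests were adjusted by the Benjamini-Hochberg method over the 13 arms, or over the 5 large arms for the position along an arm. Median values on the X and on the autosomal arms were compared by permuting the arm labels of 500 kb blocks 1000 times. The correlation of values between replicates was tested with 100000 permutations. Mean values are given with the SD of the 2 replicates. No test between ChIP and input libraries was made, because the inputs have no values of their own in the files used here, and the p-values describe these lists.

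The procedures were tested on simulated lists with the real widths in random places. Of 100 pairs of unrelated lists on arms 2L and 4, 6% reached p under 0.05 in the overlap test of covered bases (Jaccard index). No such rate was computed for the share of shared clusters. Of 100 lists with no change at the centromeric end of 2L, 4% reached p under 0.05 in the test of position. After 50% of the clusters there had been removed 100% did, with a mean ratio of 0.50. For the block permutation the values were shuffled over the clusters. It called 4% of 100 unchanged lists and 100% of 100 lists with 0.05 added to the log2 values on the X. The test of depleted regions by arm called 55% of 100 lists of evenly placed regions from which most of those on the X had been removed. Random places and shuffled values lack the unevenness along the arms that the real lists have. These rates may therefore not hold for the real lists.

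Before the data were examined, the tests, the alternatives and a rule for the items to name were fixed. The rule took the 10 clusters of the combined list with the highest value and the 10 widest. Gene lists, classes of gene annotation and profiles around gene starts had also been planned. They were not run, because the gene table at hand is on release 6 of the genome while the regions are on release 5, and no coordinates were converted. Regions are therefore named by position. The alternatives were a stricter threshold (values at or above the median of the list), a minimum width of 1000 bp, an overlap of 1 bp or 80%, merging of clusters closer than 500 bp, pericentric ends of 1 or 4 Mb, use of the combined list, and leaving out each replicate. The comparison of the X with the autosomes, the test of the 5 large arms together, the classes of combined clusters by value and width, the chance level of their recovery, the chance overlap by class of arms, the tests of depleted regions, and the restriction to the 6 main arms outside the overlap test were added after the data had been seen.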

Results

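Enrichment of histone H3 over input was measured in nuclei of larvae, in 2 ChIP replicates with 1 input each. H3-enriched clusters covered 34.1% of the assembly in replicate 1 and 37.6% in replicate 2. Replicate 1 had 18082 clusters over 47.7 Mb and replicate 2 had 18625 clusters over 52.5 Mb, a mean of 50.1 ± 3.40 Mb (SD, n = 2) or 35.8 ± 2.43% (SD, n = 2) of the 13 arms analysed. The clusters had a median width of 2037 bp in replicate 1 and 2112 bp in replicate 2. The widest reached 29332 bp and 31550 bp. Enrichment over input was modest, with a median log2 value of 0.55 in replicate 1 and 0.54 in replicate 2. The list that the authors made for the replicate set was larger, with 23076 clusters over 69.9 Mb, 50.0% of the assembly, and a lower median log2 value of 0.40. Its narrowest cluster had 1001 bp, against 1301 bp in both replicate lists. Sequencing depth is unknown for these lists, and differences in the number of clusters between them cannot be separated from depth.

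The replicates marked largely the same places. Of the clusters of replicate 1, 88.5% were covered over at least 50% of their length by clusters of replicate 2, and 81.0% of those of replicate 2 were covered by replicate 1. Circular shifts gave means of 43.5% and 39.1% and never more than 45.2% and 40.6% (one-sided permutation p = 0.001 for both, the smallest the shifts can give). The Jaccard index of covered bases was 0.729, against a mean of 0.252 and a maximum of 0.269 over the shifts (one-sided permutation p = 0.001). On the 6 main arms 89.0% (95% Wilson interval 88.6 to 89.5%) of replicate 1 clusters were shared. The share was 77.3% (72.7 to 81.3%) on the Het arms of mapped heterochromatin and 67.6% (61.2 to 73.3%) on U, the unplaced scaffolds. For replicate 2 the same shares were 81.6%, 73.0% and 52.6%. Chance overlap differed between these classes of arms, since shifts within them gave means of 44.6%, 9.72% and 5.86% for replicate 1 and 40.2%, 8.96% and 4.52% for replicate 2. Each class exceeded its highest shift in both replicates (one-sided permutation p = 0.001, the smallest the shifts can give). Differences between the classes were not tested. Shifts place clusters on any base, also where reads may not be placeable, so these means may understate chance overlap. Clusters without a base in the other replicate, 1731 in replicate 1 and 3020 in replicate 2, were narrower and weaker than shared ones. In replicate 1 their median width was 1469 bp against 2151 bp, and their median log2 value was 0.45 against 0.55.

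The strength of shared clusters also went together between the replicates. Over 15847 pairs of overlapping clusters, Pearson's r was 0.777 and Spearman's rho was 0.734 (permutation p = 1e-05 for each, also after Benjamini-Hochberg adjustment over both, the smallest 100000 permutations can give). This is a correlation across clusters, which are not independent replicates. The median difference of replicate 2 minus replicate 1 was 0.02 log2 units, with an SD of 0.13 over pairs.

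The combined list held nearly all replicate clusters and many others. It covered at least 50% of the length of 99.5% of replicate 1 clusters and 99.4% of replicate 2 clusters. In the other direction, 12763 of its 23076 clusters, 55.3% (95% Wilson interval 54.7 to 55.9%), were covered over at least 50% of their length by both replicates, against a mean of 33.6% and a maximum of 34.6% over circular shifts. A further 7.29% were covered by replicate 1 alone and 13.3% by replicate 2 alone. The remaining 5566, 24.1%, were covered by neither. When 80% of the length had to be covered, both replicates covered 33.8%. The clusters covered by both had a median width of 3039 bp, and those covered by neither had 1260 bp. The combined list is taken to cover the same ChIP replicates. Coverage above the shifts may follow from that and is not independent evidence for its clusters.

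Broad domains were recovered best and the highest values worst. Of 527 combined clusters of at least 10 kb, 518 were covered over at least 50% of their length by both replicates, and the other 9 by replicate 2. Among clusters with log2 values between 0.5 and 1, 87.5% were covered by both replicates. This share was 43.4% among 15809 clusters of up to 0.5, 21.9% among 517 clusters above 1 and up to 2, and 2.99% (1.17 to 7.42%) among 134 clusters above 2. Of those 134, 104 had no base in a cluster of either replicate. For the clusters of up to 0.5, circular shifts gave a mean of 35.3% covered by both replicates and a maximum of 36.5%. This comparison too is not independent, as the list is taken to cover the same replicates. No chance level was computed for the classes above 0.5 or for the broad domains, and the classes differ in width.

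**Figure D1:**
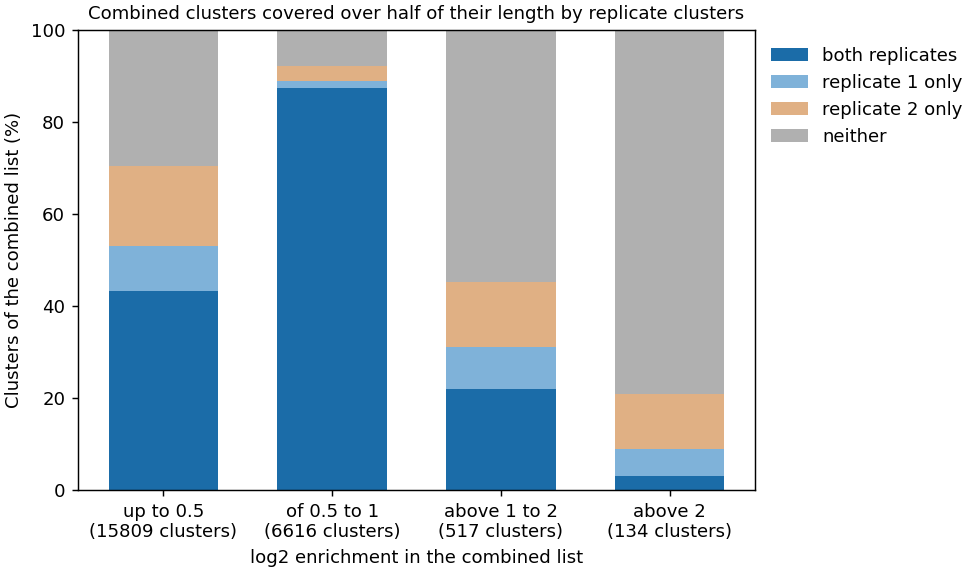
Clusters of the combined list (percent, y axis) by their log2 enrichment (x axis), split by whether clusters of both replicates, of 1 replicate or of neither cover at least 50% of their length. The share covered by both is 87.5% between 0.5 and 1 and 2.99% above 2.

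The widest combined cluster lay on 2R from 20722808 to 20762504 (39.7 kb, log2 value 0.75), and replicate 1 covered 97.0% and replicate 2 96.4% of it. Of the 10 widest, 6 lay on the X, all of these within its first 3 Mb. They included the region from 1293802 to 1333424 (39.6 kb, log2 value 0.86) and the region from 1598578 to 1630088 (31.5 kb, log2 value 1.02), of which replicate 1 covered 87.1% and 96.1%. The other 3 were on 3L from 1755974 to 1793906 (37.9 kb, log2 value 0.85), on 3R from 20461638 to 20494622 (33.0 kb, log2 value 0.74) and on 2R from 4695672 to 4727226 (31.6 kb, log2 value 0.82). Each of the 10 was covered over at least 86.3% of its length by each replicate. Of all clusters of at least 10 kb, 2R held 125 at 17.6% of the length of the 6 main arms and 3R 138 at 23.2%. The X was not overrepresented among them, with 95 of the 527 at 18.6% of that length.

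The 10 clusters with the highest values were short and lay mostly on unplaced scaffolds. Of these, 7 were on U, and 1 each on 2R, 2L and 3LHet. The highest value, 4.02, was shared by a cluster on 2R from 2234316 to 2236320 and one on U from 9749316 to 9750778. The cluster on 3LHet ran from 1257296 to 1258304 (log2 value 3.28) and that on 2L from 20746468 to 20747594 (log2 value 3.16). Neither replicate had a base of a cluster in any of the 10.

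Between chromosome arms, coverage was high on the large euchromatic arms and low on heterochromatin and on chromosome 4, a small chromosome rich in heterochromatin. Clusters covered 46.8 ± 3.10% of 2R, 46.3 ± 2.86% of 3R, 38.1 ± 2.05% of 3L, 37.1 ± 3.86% of the X and 35.3 ± 1.88% of 2L (SD, n = 2 for each). They covered 5.52 ± 0.055% of chromosome 4, 9.18 ± 0.53% of the Het arms together and 5.30 ± 0.96% of U (SD, n = 2 for each). The lowest share was on YHet, the mapped part of the Y chromosome, with 2.05 ± 0.73% (SD, n = 2), which rested on 3 clusters in each replicate. In every one of these arms the 2 replicates lay closer to each other than the large arms lay to chromosome 4 or to U.

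Against circular shifts over the joined arms, 0 of the 13 arms passed the test after Benjamini-Hochberg adjustment, and 2 had an unadjusted permutation p under 0.05. These were U, with a ratio of its covered share to that of the whole assembly of 0.147 (two-sided permutation p = 0.01, adjusted 0.13), and YHet, with 0.0568 (p = 0.024, adjusted 0.156, permutation). In the combined list these ratios were higher, 0.291 for U and 0.137 for YHet. The ratio of chromosome 4 was 0.154 (adjusted permutation p = 0.286). Its call changed with the arms compared. With shifts and adjustment over the 6 main arms alone the ratio was 0.137 and the adjusted permutation p was 0.012. In the combined list the ratio was 0.167 and the adjusted permutation p was 0.026. Over the 6 alternatives that changed the clusters or the arms the adjusted permutation p ranged from 0.012 to 0.793. In the joined order, chromosome 4, the Het arms and U lie next to each other. Shifts can therefore place one arm of low coverage on another, which makes the test hard to pass for these arms. Not passing it does not show that their coverage was like that of the large arms. How reads from repeated sequence were placed is not known here.

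**Figure D2:**
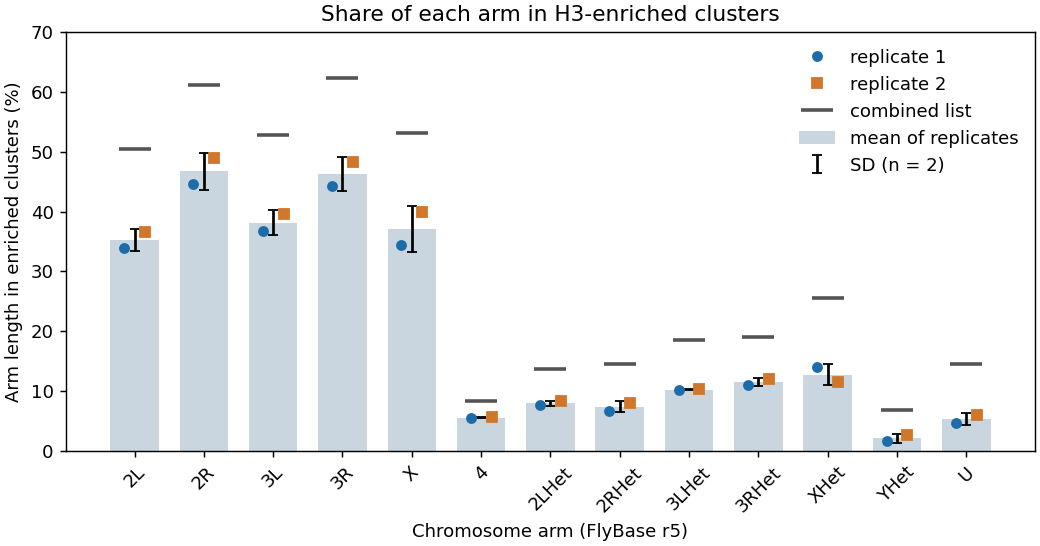
Share of each chromosome arm (percent of its length, y axis) in enriched clusters. Bars give the mean of 2 replicates with their SD, points the replicates, and dashes the combined list, and the large arms at 35.3 to 46.8% stand above chromosome 4 at 5.52%.

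On each of the 5 large arms, the part next to the centromere had a lower covered share in both replicates. In the 2 Mb nearest the centromere, clusters covered 17.4 ± 0.75% of 2L against 37.0 ± 1.99% of the rest of the arm, 21.0 ± 1.49% against 49.4 ± 3.27% on 2R, and 20.5 ± 1.12% against 39.7 ± 2.14% on 3L (SD, n = 2 for each). The X had 25.2 ± 2.86% against 38.3 ± 3.95%, and 3R had 44.1 ± 2.89% against 46.4 ± 2.86% (SD, n = 2 for each), with 42.1% against 44.4% in replicate 1 and 46.2% against 48.5% in replicate 2. Tested arm by arm, no ratio passed after adjustment. The ratios were 0.471 on 2L (adjusted permutation p = 0.0599), 0.426 on 2R and 0.516 on 3L (0.0799 for both), 0.658 on the X (0.107) and 0.950 on 3R (0.909), and 3 had an unadjusted permutation p under 0.05. With the 5 arms tested together, a test chosen after the single arms had been seen, the mean ratio was 0.604, below the lowest shifted value of 0.681 (two-sided permutation p = 0.002, the smallest the shifts can give). The ratios depended on the size of the end: for 4 Mb they were 0.803 on 2L, 0.727 on 2R, 0.870 on 3L and 0.864 on 3R, and the X turned to 1.02. For 1 Mb they were 0.471 on 2L, 0.337 on 2R, 0.354 on 3L, 0.788 on 3R and 0.440 on the X. No arm passed after adjustment at either size. Whether reads could be placed throughout these ends is not given in the sources used here. Shifts move clusters over any base, so they do not account for this. A low covered share near the centromere need not mean low enrichment.

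In 236 full windows of 500 kb on the 5 large arms, the covered share ranged from 9.99% to 74.0%, with a median of 41.0%. Replicate 1 was below replicate 2 in 219 of the 236, and across windows Pearson's r between the replicates was 0.985. The lowest window lay inside 3L from 18 to 18.5 Mb (9.99 ± 0.27%, SD, n = 2), away from the centromere. Next were 3L from 24 to 24.5 Mb (10.7 ± 0.76%), 2R from 1 to 1.5 Mb (13.5 ± 1.00%) and X from 21.5 to 22 Mb (14.3 ± 2.83%), all close to the centromere, and 2L from 17 to 17.5 Mb (14.4 ± 0.40%, SD, n = 2 for each). The highest windows were 2R from 20 to 20.5 Mb (74.0 ± 2.73%), X from 1 to 1.5 Mb (69.3 ± 6.87%), 2R from 4.5 to 5 Mb (69.0 ± 1.76%) and 2L from 0.5 to 1 Mb (68.6 ± 2.97%, SD, n = 2 for each).

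**Figure D3:**
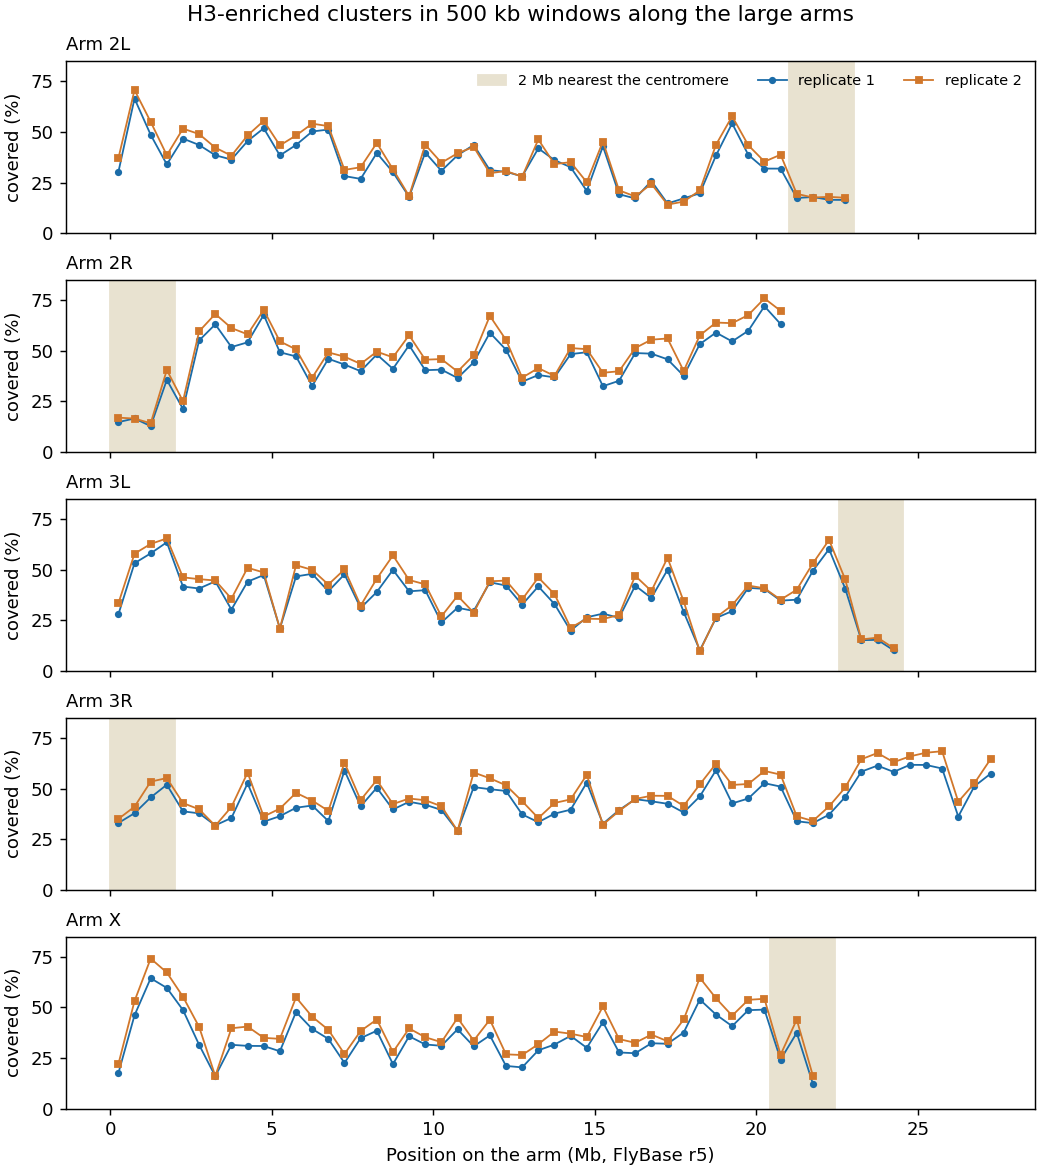
Share of 500 kb windows in enriched clusters (percent, y axis) along the 5 large arms (Mb, x axis) for both replicates, with the 2 Mb nearest the centromere shaded. The shaded ends of 2L, 2R and 3L average 17.4 to 21.0%, and that of 3R averages 44.1%.

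The longest stretch of a large arm without a cluster in the combined list was on 2L from 21410083 to 21529421, 119 kb, within the 2 Mb nearest the centromere. It was followed by 2R from 2236321 to 2319617 (83.3 kb), X from 21687139 to 21758725 (71.6 kb) and X from 15896627 to 15964473 (67.8 kb). Neither replicate had a cluster in any of these 4 stretches. Whether reads could be placed there is not given in the sources used here. Missing clusters in these stretches therefore need not mean missing enrichment. The 2R stretch begins at the base after the cluster with the highest value on that arm.

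The clusters of the X carried higher values than those of the autosomes. The median log2 enrichment was 0.61 ± 0.0083 on the X and 0.52 ± 0.0037 on the 4 large autosomal arms together (SD, n = 2 for each), a difference of 0.083 ± 0.0046 (SD, n = 2) or 1.06-fold. It was 0.086 in replicate 1 and 0.080 in replicate 2. When the arm labels of 500 kb blocks were permuted, the largest difference was 0.029 (two-sided permutation p = 0.001, the smallest 1000 permutations can give). Among clusters with values at or above the median of their list the difference was smaller, 0.036 (two-sided permutation p = 0.001). A single cutoff for the X and the autosomes can itself narrow a difference of medians. Among clusters of at least 5000 bp the difference was larger, 0.116 (two-sided permutation p = 0.001). In the combined list the medians were 0.44 and 0.38. The X also had the larger spread between replicates: the SD of replicate 2 minus replicate 1 over shared clusters was 0.15 on the X and 0.12 on the autosomes.

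The few clusters on heterochromatic and unplaced arms had higher values still, except on chromosome 4. The median log2 value of the Het arms together was 0.73 in both replicates, and that of U was 0.97 and 1.15. Chromosome 4 had 0.47 and 0.45, below each large arm in both replicates.

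**Figure D4:**
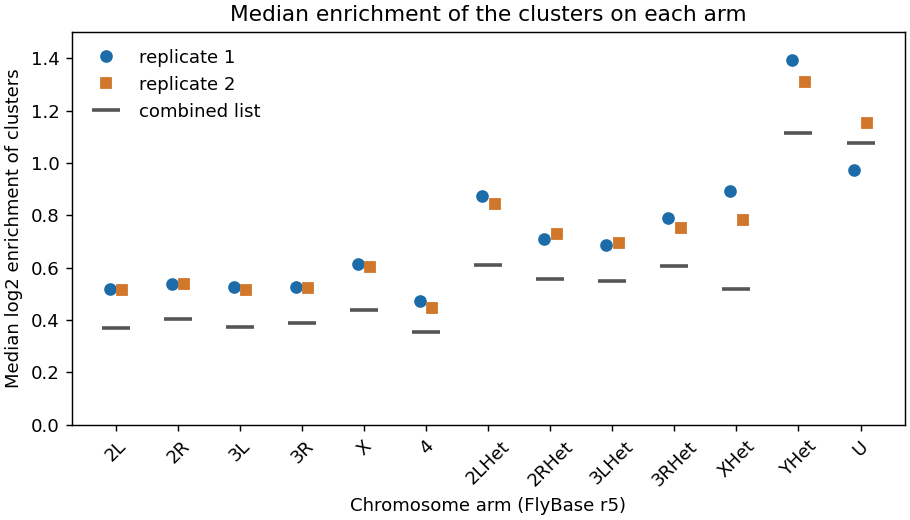
Median log2 enrichment of clusters (y axis) on each chromosome arm (x axis) in the 2 replicates and the combined list. The X lies at 0.61 and 0.60 in the replicates, above the other 4 large arms.

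Regions labelled as depleted were few and weak. Replicate 1 had 3, replicate 2 had 10 and the combined list had 256, with a median width of 1509 bp and a median log2 value of -0.04. The lowest value was -0.19, on 2R from 2615594 to 2617120. Only 1 place was labelled as depleted in both replicates, on 3R from 10386191 to 10387789 in replicate 1 (log2 value -0.02) and from 10386131 to 10387724 in replicate 2 (-0.09), and it was not among the depleted regions of the combined list. On the 6 main arms, 16 of 254 depleted regions of the combined list lay on the X, against 47.3 by its length. The other large arms had 44 to 70. The shortage on the X did not pass the test against circular shifts (two-sided permutation p = 0.0639, adjusted over 5 arms 0.32). Among the 128 with the lowest values, 5 lay on the X, against 23.8 by its length (two-sided permutation p = 0.0959). Of the 256, 138 had a base in an enriched cluster of at least 1 replicate.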

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

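The restriction to the 6 main arms outside the overlap test, the count with Uextra, the limit on the width of combined clusters, the 5 arms together and the alternatives for the X and for depleted regions were chosen after the data had been seen. The minimum width of 1000 bp removed no cluster, and the Jaccard index does not depend on the overlap required, so these settings test nothing and are not counted. Of 103 recomputed values of results that had not passed their test, 95 kept their direction without passing, 2 passed and 6 changed direction. The mean share of shared clusters (73.4 to 87.1%), Spearman's rho of the values (0.567 to 0.758), the ratio of the 5 pericentric ends together (0.478 to 0.857) and the excess of the X (0.036 to 0.116) kept their direction and passed in each of their alternatives, as did the Jaccard index, 24 recomputed values in all. With values at or above the median of the list, the mean number of clusters was 9177.5 (from 18353.5), the covered length 32.3 Mb, the median width 2866.5 bp and the share of combined clusters covered by both replicates 47.2%. The first 2 of these follow from the removal of the weaker clusters. Merging clusters closer than 500 bp gave a mean of 14847 clusters and a median width of 2301.5 bp, and the 6 main arms alone held 17730 clusters. The share of combined clusters covered by both replicates was 59.6% with an overlap of 1 bp, 33.8% with 80%, 64.7% among combined clusters at least as wide as the narrowest replicate cluster and 57.3% on the 6 main arms. With 1 replicate left out it was 62.6 to 68.6%, as only 1 replicate then has to cover a cluster. Arms close to the average of the assembly changed side of 1 without passing the test: 2L from 0.985 to 1.01 in the combined list and to 1.19 when Uextra was counted, 3L from 1.06 to 0.978 at the stricter threshold and to 0.943 among the 6 main arms, and the X from 1.03 to 0.917 among the 6 main arms. Counting only the main arms or adding Uextra changes the average itself; for the others the cause was not tested. Chromosome 4 passed the test in the combined list (ratio 0.167), where the cause was not tested. It also passed among the 6 main arms (0.137). There the other arms of low coverage were left out of the shifts, and the adjustment ran over 6 arms. How much each of these contributed was not tested. At 4 Mb the pericentric end of the X reversed to 1.02 and the ratios of 2L, 2R, 3L and 3R were 0.803, 0.727, 0.870 and 0.864. The larger end took in better covered windows. Among these were X from 19500001 to 20000000 (51.2%), 2L from 19500001 to 20000000 (41.1%), 2R from 3000001 to 3500000 (65.7%) and 3L from 22000001 to 22500000 (62.4%). On 3R the ratio fell instead, and the window from 3000001 to 3500000 had 31.7%. At 1 Mb the ratios were 0.337 to 0.788. No paired analysis was possible because the input libraries have no values of their own in the files used here, so the comparison of each ChIP with its input of the same number could not be run as a block. The planned analyses of gene annotation, gene starts and gene lists were not run, and their alternatives with them. Depth is unknown, which leaves open how many of the clusters found in a single list were missed in the others for want of reads.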

Other observations

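The tests of the 10% level, of the replicate spread and of the pericentric end of the X were set before their own results were seen, but the test of the 10% level replaced one on wide clusters whose result (a difference of 0.116) was known; those of shared values, of widths, of the depleted regions and of the weakest clusters were chosen after. The weakest combined clusters lay less often on clusters of both replicates than by chance, unlike the combined clusters as a whole. Among the 801 with log2 values under 0.1, 17.0% were covered over at least 50% of their length by both replicates, against 30.6 to 41.8% over circular shifts. Those covered by 1 replicate alone made up 16.4% for replicate 1 and 26.3% for replicate 2, above the highest shifts of 6.62% and 10.9%, and 40.3% were covered by neither, against 45.8 to 57.9% over the shifts. Coverage by a single replicate also exceeded the highest shifts among all combined clusters (7.29% against 4.33% and 13.3% against 8.53%). The combined list is taken to cover the same ChIP replicates, and the weakest clusters were picked by their own value. These departures from the shifts may follow from that, and no conclusion is drawn from them.

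The higher enrichment of the X was weighed against 3 technical explanations. If a higher level were needed for a call on the X, the strongest clusters covering an equal share of the length should have equal values. At 10% of the length the X stood 0.099 log2 units above the autosomes. The largest permuted difference was 0.060 (two-sided permutation p = 0.001). This argues against the explanation only if the level needed leaves the values of strong clusters unchanged. It cannot exclude it if values are means over regions, because a higher level at the edges could raise these too. The pericentric end did not account for the higher values, since without its 4 Mb the difference was 0.082 (two-sided permutation p = 0.001). Noisier values remain open: the SD of the difference between replicates was 1.205 times as large on the X, only just past the bound of 1.2 set for this explanation, with a median absolute deviation 1.24 times as large, and fewer reads on the X could raise a value if it is a maximum over its region. A biological difference between X and autosomes was not tested.

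The highest values of the combined list, mostly absent from both replicates, may rest on few reads. Of the 134 clusters above a log2 value of 2, 86.6% had exactly the same value as another cluster of the list, against 26.9% of the others, as ratios of small counts would give; the share was 95.2% among the 104 with no base in a replicate cluster and 56.7% among the 30 with one. The smaller width limit of the combined list is not the whole explanation, since 55.9% (33 of 59, exact 95% interval 42.4 to 68.8%) of those at least 1301 bp wide had no base in a replicate cluster. The share was 94.7% among the 75 narrower ones, so the width limit can account for a part. No biological explanation was tested.

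The depleted regions had values just below 0 and the weakest enriched ones just above. In all lists the label followed the sign of the value. Whether it marks more than the sign was examined through the overlap with enriched clusters of the replicates. Of the 256 depleted regions, 53.9% had a base in an enriched cluster of a replicate, below the mean of 63.5% over circular shifts but above their lowest, 53.1%. Regions labelled enriched with log2 values under 0.1 had 60.2%, likewise below the mean of 64.1% and above the lowest shift, 59.7%. This overlap leaves open whether the label marks more than the sign. The share of the depleted regions lay neither below their shifts nor at their mean. That of the weakly enriched regions also lay between the lowest and the mean of its own shifts. No biological explanation was tested.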
